A study of Homo sapiens with 2 samples.

How the data were processed

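RNA bound by ALKBH5 was measured by RNA immunoprecipitation and sequencing (RIP-seq) in HL-60, an established human promyelocytic leukaemia line, per the labels. ALKBH5 is an enzyme that removes the methyl group of N6-methyladenosine (m6A) from RNA. Per the series design text, 10% of the lysate was kept as input, 80% went to the ALKBH5 antibody and 10% to a rabbit IgG control. The labels hold 2 libraries, 1 input and 1 immunoprecipitate (IP); an IgG library was not analysed here. The title of each library names the other group than its library name does, and the groups were taken from the library names. Per the labels' protocols, the libraries were made with a stranded mRNA kit and sequenced in paired reads. The genome build was hg38 per the submitters' processing notes. The aligner, the peak caller and its thresholds, and the use made of the IgG control were not given in the sources used here.

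A set of 3 tables was used, each of the whole series. The GO and KEGG tables give, per the file headers, the number of input entries and the number of background genes of each term as the authors' own counts, and the entries themselves as a gene identifier paired with a symbol. Per the file headers, the authors also deposited a rich factor, which is a fold (the ratio of the term's share of input entries to the overall share). In every listed term the deposited rich factor equalled the share divided by 33.3%. The p-value and the corrected p-value of each term are the authors', per the file headers, and all listed terms had a deposited p-value under 0.05. The third table pairs gene symbols with families of RNA-binding proteins, per the file headers, with no number in it; how the authors made it was not given in the sources used here. The read counts of the libraries and the positions, heights and scores of single peaks were not analysed here, so the depth behind a listed gene is unknown. No difference between IP and input could be computed from these tables, and with 1 library per group there was no replicate check.

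The authors' p-values were recomputed from their counts. A one-sided Fisher's exact test of a term's input entries against its background genes, with totals of 11725 and 30938 annotations in KEGG and of 107901 and 268727 in GO, gave every deposited p-value to within 3.14e-11 on the log10 scale. The totals were solved for from the deposited values. The corrected p-values equalled a Benjamini-Hochberg adjustment over 325 KEGG pathways and 6846 GO terms, more than the 38 and 311 listed. Since several symbols can carry the same gene identifier while the background counts genes, the same test was run with each identifier counted once. This alternative was chosen after seeing the data. So were a test with the input total scaled to distinct identifiers and a one-sided hypergeometric test over genes. Corrected values of the scaled and hypergeometric tests, and those of the Fisher test by distinct identifier at or above 0.05, are upper bounds, because terms that were not listed could only lower them. The p-values describe the overlap of gene lists and not the spread between experiments.

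A gene was called listed when any of the tables named it. Symbols were matched to the RefSeq gene table of GRCh38.p14, the reference used here, by symbol and then by older symbols; 362 of the 5851 symbols had no match. Gene lists fixed before the data were examined (17, with ribosomal protein and histone genes among them) were compared with 10000 random lists of the same size drawn from 20056 protein-coding genes, as a description with a fixed seed. A list was set apart when its count lay above the 97.5th percentile or below the mirror of that limit; with 16 lists scored, chance alone places some there. Apart from 237 symbols of the family table alone, a symbol was seen only in a GO or KEGG term that reached the authors' limit, so an unlisted gene may still have had a peak. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Alternatives were a background of genes of any biotype and random lists matched on genomic gene length, introns included, in 10 bins. The background of any biotype lowers the expected count of each list of protein-coding genes. Further alternatives were GO or KEGG genes alone, the family table alone, and the family table among genes named in the GO or KEGG table. Listing was also repeated without the terms holding AMBRA1's identifier that lost a p under 0.05 by distinct identifier, and with only those terms that kept one. These last 2, the GO or KEGG genes alone and the family table alone were chosen after seeing the data.

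The rule for naming genes and terms was fixed before the data were examined. It took ALKBH5, up to 6 listed members of each fixed list in alphabetical order (no value ranks them), the 5 GO terms of smallest p per branch, the 10 KEGG pathways of smallest p, and each term whose name holds a word on autophagy, the lysosome, mTOR, AMPK, FoxO, apoptosis, neutrophils, granulocytes, rheumatoid disease, m6A or demethylases. The parts of the rule that rank genes by enrichment or number of peaks could not be used. Unlisted members of the lists, members beyond the first 6, the symbols that share an identifier, and the GO terms and KEGG pathways beyond the rule were named after their values were seen. Not every gene that the rule allows was named, and 1 is not reported here.

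The procedures were tested on simulated data. Of 30 simulated KEGG pathways with a doubled share, 17 were called at a Bonferroni-adjusted p under 0.05 and 0 of 295 unchanged ones were. After 50 extra symbols were put on 1 identifier, 292 of the 295 unchanged pathways were called. This outcome was nearly fixed in advance, because 50 was added to the count of each pathway. The simulation also used totals of genes and not the annotation totals of the recomputed test. Of 500 unchanged lists of 45 genes 12 lay above the percentile limit, as did 94 of 100 lists with a doubled share. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.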

Results

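The data came from HL-60 cells, a human promyelocytic leukaemia line often used as a model of neutrophil precursors. RNA held by an antibody against ALKBH5, the m6A demethylase, was sequenced beside the RNA of the whole lysate, with 1 library of each. The GO and KEGG tables named 5614 gene symbols on 5237 distinct gene identifiers. The family table named 1348 symbols, of which 1111 were also in the GO or KEGG table. Together the tables named 5851 symbols. The tables give no level per gene and no value per library, so genes are described as listed or not listed.

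ALKBH5 transcripts were themselves listed. The gene lies on chromosome 17 from 18183828 to 18209954 (GRCh38.p14), and its entries included the GO terms RNA binding, nuclear speck, mRNA processing, mRNA export from nucleus and regulation of mRNA stability. Of the 25 genes of the m6A machinery, 21 were listed (84%, 95% interval 63.9 to 95.5%). They included FTO, the other known m6A demethylase, the RNA-binding proteins FMR1, HNRNPA2B1 and HNRNPC, and the reader IGF2BP1. The unlisted members were CBLL1, METTL5, YTHDF3 and IGF2BP2. No random list of the same size held as many, and 16 of them were entries of the term RNA binding. In the family table alone, 2 of the 25 were present (1.30-fold of the expected count, percentile 67.3), and among genes named in the GO or KEGG table its share of the list was 0.475-fold of that expected (percentile 11.7). The GO term histone demethylase activity (H3-K36 specific) had 10 entries on 10 genes and a corrected p of 0.957 in the authors' deposited table.

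The first comparison asked which cellular functions the genes with peaks belong to. Terms of RNA metabolism and of nuclear compartments were among the leading ones, beside cytosol and membrane. In the authors' deposited table, 821 entries fell on the 1366 background genes of RNA binding, with a corrected p of 5.33e-16 and a rich factor of 1.80. Nucleoplasm had 1939 entries on 3630 genes in the authors' deposited table (corrected p 3.05e-20), and nuclear speck, the compartment rich in splicing factors, 259 on 400 (2.04e-06). Among processes, mRNA splicing via the spliceosome had 165 entries on 246 genes (1.98e-04) and DNA repair 155 on 224 (1.25e-04) in the authors' deposited table. The viral process term had 291 entries on 456 genes (corrected p 7.46e-07) in the authors' deposited table. In the same branch autophagy had 119 entries on 126 genes (4.22e-08) and macroautophagy 90 on 93 (2.58e-06) in the authors' deposited table.

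Cytosol (corrected p 5.90e-11), membrane (6.31e-10) and nucleolus (1.15e-07) completed the leading compartments of the authors' deposited table. ATP binding (6.03e-11), ubiquitin protein ligase binding (4.93e-06), cadherin binding (0.00398) and ATPase activity (0.00498) completed its leading molecular functions. In all, 38 of the 311 GO terms of the authors' deposited table had a corrected p under 0.05, 13 of them processes, 13 compartments and 12 molecular functions. With each gene identifier counted once, 16 of these 38 terms stayed under 0.05 in the Fisher test with the authors' input total. Of all 311 listed terms, 26 were under 0.05 with that total scaled to distinct identifiers and 288 in the hypergeometric test over genes by distinct identifier. RNA binding (782 of 1366 genes, 57.2%, 95% interval 54.6 to 59.9%), nucleoplasm, nuclear speck (61.0%), mRNA splicing (64.2%), DNA repair (64.3%) and viral process (58.8%) were among the 16. DNA replication (92 of 131 genes, 70.2%), rRNA processing (68.1%), mRNA export from nucleus (73.3%) and RNA helicase activity (79.7%) were as well. Ubiquitin protein ligase binding, cadherin binding and ATPase activity were not, nor were autophagy and macroautophagy.

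Autophagy, the pathway by which cells degrade their own contents in lysosomes, led the KEGG table. The authors' deposited table gave it 116 entries on 128 background genes, with a corrected p of 6.01e-09. These 116 entries stood on 59 distinct gene identifiers, 46.1% of the pathway (95% interval 37.2 to 55.1%). AMBRA1, a scaffold that activates the start of autophagy and lies on chromosome 11 from 46396412 to 46594023 (GRCh38.p14), accounted for most of the gap, since 50 other symbols carried its identifier. Among them were B2M, the light chain of class I major histocompatibility molecules, the interferon-induced MX2, the tropomyosin TPM4, and antisense transcripts such as VAC14-AS1. With each identifier counted once, the one-sided Fisher's exact p of the pathway was 0.122, and 36 of the other 37 pathways had a smaller p. With the input total scaled to distinct identifiers as well, the Fisher p was 0.0556. The hypergeometric test over genes by distinct identifier kept the corrected p under 0.05 (at most 0.0169). That test did so for all 38 listed pathways, so it does not set autophagy apart.

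**Figure D1:**
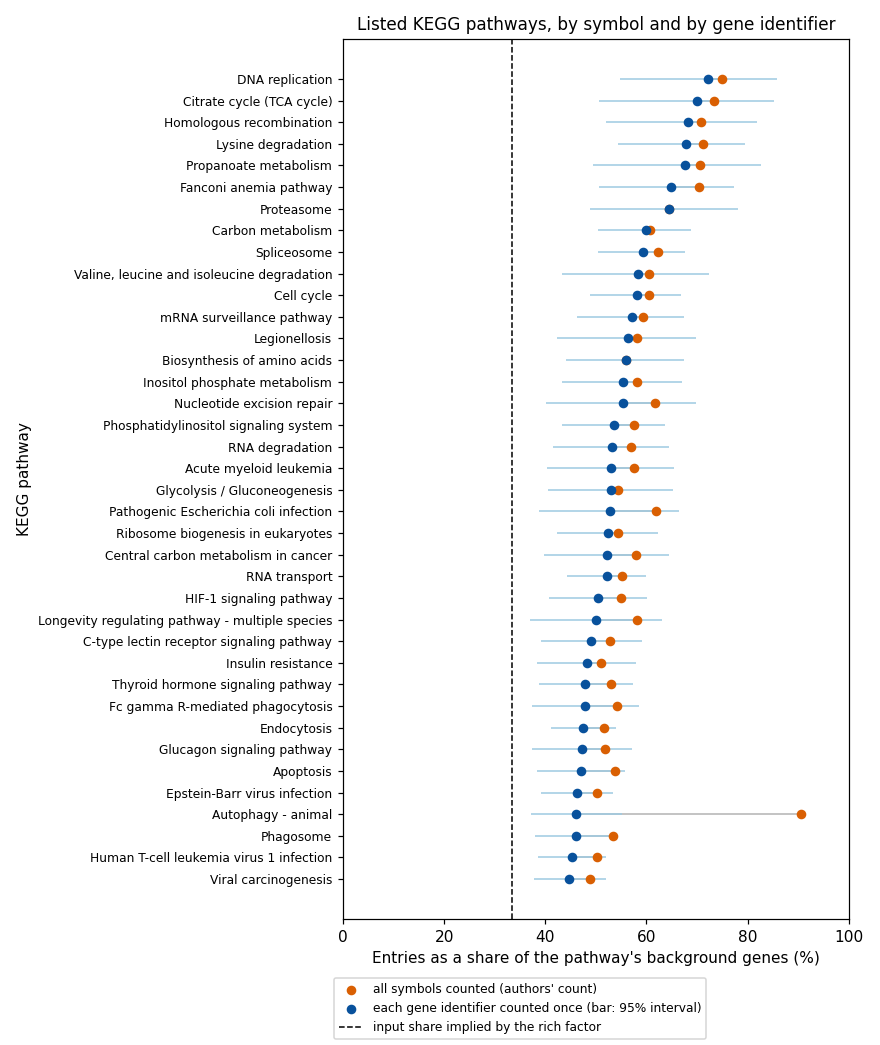
Share of each listed KEGG pathway's background genes (horizontal axis, percent) taken by the entries of the authors' deposited table, for the 38 listed pathways (vertical axis). Orange points count all symbols and blue points count each gene identifier once, with exact 95% intervals that cover counting error only. The dashed line is the 33.3% by which the deposited rich factor divides a share. It is not the baseline of the Fisher test, whose KEGG totals were 11725 and 30938. Autophagy moves from 90.6% to 46.1%, while no other pathway holds more than 1.17 symbols per identifier.

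Members of the pathway with identifiers of their own were listed beside these. They included ATG13, of the kinase complex that starts autophagy, ATG16L1 and ATG16L2, which direct the lipidation of LC3, and the lipid transfer proteins ATG2A and ATG2B. Of the 45 genes of the core autophagy list 16 were listed (35.6%, 95% interval 21.9 to 51.2%), against 12.1 expected, at percentile 89.8 of random lists. BECN1, ATG5, ATG12 and the LC3 and GABARAP genes were not listed. Of the 22 autophagy receptors and mitophagy genes 6 were listed, against 5.92 expected: SQSTM1, OPTN, NCOA4, WDFY3, PINK1 and RTN3. Neither list stood apart from random lists of protein-coding genes. Against genes of any biotype, where expected counts are lower, both did (3.88-fold at percentile 100 and 2.97-fold at percentile 99.1).

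Of the 54 genes of mTOR and AMPK signalling, the nutrient and energy sensors, 23 were listed (42.6%, 95% interval 29.2 to 56.8%), at percentile 99.2. AKT1, AKT2, AKT1S1, CAMKK2, DDIT4 and DEPDC5 were among them. Of the 23, 14 were entries of KEGG autophagy; without the AMBRA1 terms that lost a p under 0.05 by distinct identifier, all 23 were still listed (percentile 99.6). Of 49 lysosomal genes 24 were listed (49.0%, percentile 99.9), with the proton pump subunits ATP6V0A1, ATP6V0A2, ATP6V0D1, ATP6V1A and ATP6V1B2. In the family table alone, 3 of the 49 were present, 0.997-fold of the expected count (percentile 52.9), and it held 0.624-fold of that expected among genes named in the GO or KEGG table (percentile 19.2). No KEGG pathway named for the lysosome, mTOR, AMPK, FoxO or mitophagy was among the 38 listed. Any such pathway that was tested therefore missed the authors' limit for listing. Other terms with related names did not reach a corrected p of 0.05 in the authors' deposited table. They were negative regulation of autophagy (31 entries on 50 genes, corrected p 0.972), endosome to lysosome transport (31 on 47, 0.797), protein targeting to lysosome (14 on 18, 1) and the KEGG pathway Apoptosis (73 on 136, 0.236). Negative regulation of neuron apoptotic process had a corrected p of 0.00654 in the authors' deposited table with 97 entries, and 43 distinct identifiers on 138 genes (31.2%), with an unadjusted one-sided Fisher p of 0.94 once each was counted once.

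The remaining KEGG pathways were led by RNA processing, the cell cycle and metabolism. Spliceosome had 84 entries on 135 genes and a corrected p of 0.0486 in the authors' deposited table, the only pathway beside autophagy under 0.05. Cell cycle, Carbon metabolism and Lysine degradation had a corrected p of 0.1 in the authors' deposited table. RNA transport, Fanconi anemia pathway and Endocytosis had 0.127 there, and DNA replication and mRNA surveillance pathway 0.213, all in the authors' deposited table. Counted by distinct identifier, DNA replication had the highest share (26 of 36 genes, 72.2%, 95% interval 54.8 to 85.8%), and Spliceosome reached 59.3%. No pathway had a corrected Fisher p under 0.05 with each identifier counted once, and 19 had an unadjusted p under 0.05. The hypergeometric test over genes by distinct identifier gave all 38 listed pathways a corrected p under 0.05.

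Of 33 genes for neutrophil receptors, the oxidase and extracellular traps, 17 were listed (51.5%, 95% interval 33.5 to 69.2%, percentile 99.9), among them CD14, CXCR4, FCAR, FCGR1A, the oxidase subunit CYBB and the pore-forming GSDMD. The list did not stand apart in the family table alone (percentile 76.1) or in that table among genes named in the GO or KEGG table (0.881-fold, percentile 42.2). Of 32 granule protein genes 5 were listed (15.6%, 95% interval 5.28 to 32.8%, percentile 6.82, or 29.6 among genes of similar length, and 1.70-fold of the expected count at percentile 88.5 against genes of any biotype): MPO, PRTN3, LYZ, LCN2 and RNASE2. ELANE, AZU1 and CTSG, further proteins of the primary granules, were not. The granule list fell to 3 genes and percentile 1.31 when terms had to keep a p under 0.05 by distinct identifier. The GO term neutrophil degranulation had 237 entries on 482 genes and a corrected p of 0.412 in the authors' deposited table. The difference between both lists was not tested.

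Regulators of myeloid cells and of leukaemia were listed in 16 of 31 cases (51.6%, percentile 99.8), with CEBPA, CEBPB, CBFB, CD33, FLT3 and GATA2. This list did not stand apart in the family table either (percentile 78.5 alone, and 0.936-fold and percentile 47.5 among genes named in the GO or KEGG table). Of 46 genes linked to rheumatoid arthritis and cytokine signalling 26 were listed (56.5%, 95% interval 41.1 to 71.1%), against 12.4 expected. IL1B, IL6, CASP1, CSF2RB, IKBKB and IKBKG were among them, and TNF, JAK1 and JAK2 were not. In the family table this list held 0.708-fold of the expected count, and 0.384-fold among genes named in the GO or KEGG table (percentile 5.19). Of 44 cell cycle and DNA replication genes 32 were listed (72.7%, 95% interval 57.2 to 85.0%), including AURKB, BUB1, BUB1B, BUB3, CCNB1 and CCND1. Cell cycle and DNA replication were themselves listed terms, through which such genes could become listed, so the listing itself favoured a high share. In the family table this list held 0.741-fold of the expected count, and 0.312-fold among genes named in the GO or KEGG table. Apoptosis genes were listed in 11 of 30 cases, at percentile 88.1, with AIFM1, APAF1, BCL2L1, BIRC6, CASP10 and CASP2. The apoptosis list thus stayed within the limits among protein-coding genes. It stood apart against genes of any biotype, where the expected count fell to 2.75 (3.997-fold, percentile 100).

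Of 37 housekeeping mRNAs 29 were listed (78.4%, 95% interval 61.8 to 90.2%), with ACTB, ACTG1, ALDOA, B2M, CFL1 and EEF2. The family table held 0 of the 37. Of 86 ribosomal protein genes 9 were listed (10.5%, 95% interval 4.90 to 18.9%), against 23.1 expected, among them RPL3, RPL6, RPL7A, RPL14, RPL7L1 and RPS20. With random lists matched on gene length, the ribosomal protein list moved to percentile 3.8, within the limits. Against genes of any biotype it lay above the expected count (1.14-fold), because that count fell to 7.89 with the same 9 genes listed. Histone genes were listed in 16 of 87 cases (18.4%), with H1-10, H1-2, H1-3, H1-5 and H2AC21. Histone genes lay below the expected count among all protein-coding genes (0.683-fold, percentile 3.56) and above it among genes of similar length (2.11-fold, percentile 99.8) or of any biotype (2.005-fold, percentile 99.6). With only terms that kept a p under 0.05 by distinct identifier, 13 histone genes were listed (percentile 0.945). None of the 13 mitochondrially encoded protein genes was matched as listed (95% interval up to 24.7%, percentile 0.91, or 20.2 among genes of similar length). The reference writes these symbols without the MT- prefix, and the authors' symbols were matched as written. An entry with the prefix could therefore have gone unmatched, so the absence of these genes cannot be judged. None of the 19 abundant noncoding RNAs was listed, against 1.74 expected among genes of any biotype (percentile 8.31), and GO and KEGG terms annotate mainly protein-coding genes. Markers of other cell types were listed in 6 of 33 cases (18.2%, percentile 12.6, but 1.92-fold of the expected count at percentile 94.2 against genes of any biotype), namely CD4, EPCAM, KRT8, KRT18, KRT19 and PECAM1.

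**Figure D2:**
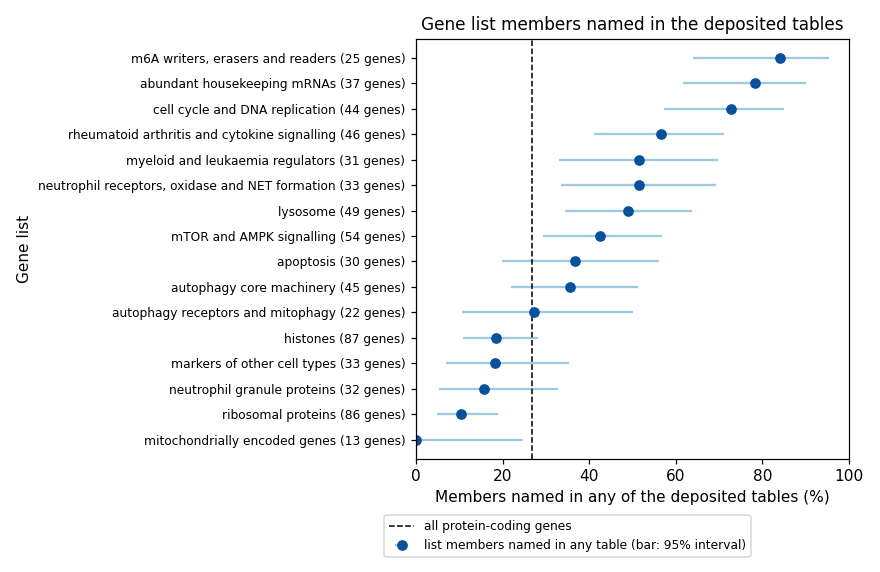
Share of the members of each fixed gene list that any of the deposited tables named (horizontal axis, percent; points with exact 95% intervals that cover counting error only), by gene list (vertical axis, with the number of protein-coding members). The dashed line marks the 26.9% of all protein-coding genes that were listed; the m6A list reached 84% and the ribosomal protein list 10.5%. The mitochondrially encoded list cannot be judged, because symbols with the MT- prefix could have gone unmatched.

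By biotype, 92.3% of the 5851 listed symbols were protein-coding genes (95% interval 91.6 to 93.0%), 1.33% were long noncoding RNAs and 6.19% had no match in the reference, so that their biotype is unknown. Listed protein-coding genes had a median genomic length of 35.4 kb, against 20.1 kb for those not listed. The family table paired its 1348 symbols with 4 families of RNA-binding proteins: the RRM family with 1348 symbols, CSD with 1342, PUF with 1183 and the combined CCHC zinc finger and RRM family with 893. A total of 838 symbols were paired with all 4 families. Since every symbol was paired with RRM, a pairing cannot be read as membership of the gene in that family. Among protein-coding genes the mTOR and AMPK list held 9 genes of this table (3.31 expected, percentile 99.7), among them RPTOR, RICTOR, TSC1, TSC2 and STK11. The core autophagy list held 6, which were ATG2A, ATG2B, ATG7, EPG5, RUBCN and ULK1 (2.76 expected, percentile 96.3). No housekeeping, ribosomal protein or histone gene was in it, and the cell cycle (0.741-fold) and the rheumatoid arthritis and cytokine lists (0.708-fold) held 2 genes each, within the range of random lists (percentiles 36.8 and 33.7). The ribosomal protein and histone lists lay below the limit there (percentile 0.205 each), and the housekeeping list did not (percentile 5.015). The family table comparisons were not matched on gene length. Protein-coding genes of the family table had a median genomic length of 41.9 kb. Among genes named in the GO or KEGG table, the family table held fewer cell cycle genes than expected (2 of 32, percentile 1.95). It held 0 of 29 housekeeping genes (percentile 0.1) and 0 of 16 histone genes (percentile 1.385), which also lay below the limit.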

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

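Tests by distinct identifier, the hypergeometric tests, the GO or KEGG genes alone, the family table alone, and both ways of leaving out terms by their p by distinct identifier were chosen after seeing the data; the other alternatives were planned. The number of symbols (5614 against 5237 identifiers) stayed within 1.5 times. The 38 GO terms under 0.05 became 16 in the Fisher test by distinct identifier and 26 with the input total scaled, 311 in the hypergeometric test by symbol, 288 by distinct identifier and 298 with the total scaled. The 2 KEGG pathways became 0 by distinct identifier, 0 with the input total scaled, and 38 in each of the 3 hypergeometric tests. Benjamini-Hochberg over the listed terms alone gave 311 and 38, which follows from listing only terms with p under 0.05. By distinct identifier the corrected Fisher p of KEGG autophagy was at most 1, and at most 0.516 with the input total scaled; for GO autophagy and macroautophagy it was at most 1 in both. The hypergeometric test by distinct identifier gave 0.0169 and 0.0156 for KEGG and GO autophagy, and for macroautophagy 1, also 1 with the total scaled. The 8 fixed lists above the limit became 12 with any biotype, 9 matched on length, 8 with GO or KEGG genes alone, 8 without the AMBRA1 terms that lost their p and 8 with only terms that kept it, where the lists below the limit rose from 2 to 4. Those 2 and 4 lists both include the mitochondrially encoded genes, whose absence cannot be judged. For the family table among genes named in the GO or KEGG table, 1 list lay above the limit and 3 below it. For the family table among protein-coding genes, 1 lay above the limit and 2 below it. Listed over expected members turned below 1 in the first of these for the lysosome (0.624), m6A (0.475), neutrophil receptor (0.881), myeloid (0.936), rheumatoid arthritis (0.384), cell cycle (0.312) and housekeeping (0) lists. In the second it did for the lysosome (0.997), rheumatoid arthritis (0.708), cell cycle (0.741) and housekeeping (0) lists. With any biotype the ribosomal proteins turned to 1.14, and lists within the limits turned above 1 as well: granule proteins (1.70), markers of other cell types (1.92) and histones (2.005). Those lists kept the same listed members while their expected counts fell, for ribosomal proteins from 23.1 to 7.89. The wider background held 59792 genes, of which 5485 were listed, so these turns follow from the background. The cause of the turns in the family table was not tested. The protein-coding share was 92.3%, and 91.5% in the family table. Stricter limits on fold, p or score, merged peaks and the stronger part of the peaks were not run, since the tables used hold no value per peak. Depth limits could not be judged without read counts.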

Other observations

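All the tests of explanations given here were chosen after the results were seen; the length-matched lists had been planned as an alternative. The test of transcript abundance was at first read from the housekeeping list alone, then from the ribosomal protein list alone, and was set to need both after both values were known.

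A total of 291 gene identifiers carried more than 1 symbol, 668 symbols in all. Most of these were small groups of at most 5 symbols, such as an antisense transcript with its host gene. Of 68 such extra symbols with a known position, 57 lay within 100 kb of the gene whose identifier they carried (83.8%, 95% interval 72.9 to 91.6%). The identifiers of AMBRA1 and C16orf89 stood apart with 51 and 21 symbols. C16orf89 itself was not listed, and its identifier was carried by HOMER2, MSI2 and MFGE8 among others; 0 of its 6 symbols with a known position lay within 100 kb. Zinc finger genes with a ZNF symbol made up 3.49% of the family table's protein-coding genes, 3.70% of the other listed ones and 2.13% of unlisted ones.

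The autophagy pathway headed the KEGG table by symbols and not by distinct identifiers. Only 19 of the 50 other symbols with AMBRA1's identifier had a known position. For these the tables argue against an origin at the AMBRA1 locus itself: 0% lay within 100 kb of AMBRA1 (95% interval up to 17.6%), and they came from 13 chromosomes. The symbols without a position are not covered. A candidate explanation is that many symbols carry 1 gene identifier and each was counted, since the unadjusted Fisher p rose to 0.122 once each identifier counted once. Whether transcripts of autophagy genes are over-represented as well stays open: the core list lay at percentile 78.7 of length-matched random lists, while the hypergeometric test by distinct identifier gave a corrected p of 0.0169, as it did under 0.05 for each of the 38 listed pathways. No biological explanation was tested, since the tables hold no contrast between groups.

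Several fixed gene lists held more listed genes than random lists. The idea that genes of long genomic span collect peaks more often is argued against as the whole cause. Once random lists were matched on that span, 9 lists lay in the top 2.5%, against 8 before, with the histones added. The span includes introns, so the length of mature transcripts was not tested. That abundant transcripts collect peaks more often cannot be told apart from other causes: 78.4% of the housekeeping mRNAs were listed but only 10.5% of the ribosomal protein genes, on either side of the 26.9% of all protein-coding genes, and no expression level was used here. Most genes could be seen only through a listed term, while random lists drew on all protein-coding genes, which may favour well-annotated genes. Listed terms had already passed the authors' p limit, so gene lists on the theme of such a term are favoured by the listing itself. No background matched on annotation was run, so the percentiles cannot separate annotation from binding by ALKBH5. The family table, which holds no terms, had 1 list above the limit among protein-coding genes. It cannot decide the question, because how that table was made was not given in the sources used here. No biological explanation was tested for these lists.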
